A study of Mus musculus with 12 samples.

How the data were processed

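RNA from mouse primary hepatocytes was hybridised to 12 Affymetrix Mouse430_2 arrays, 1 sample per array, in 4 groups of 3. Per the labels' protocols, the cells came from 8-week-old male C57BL/6J mice that were wild type or lacked Cnot6l. The series text states that every hepatocyte preparation was divided, one portion giving the input RNA and the other an RNA precipitate made with an antibody against CNOT6L (IP), and that the knockout cells served as the negative control of the precipitation. RNA was extracted with Trizol and an RNeasy kit and labelled as biotinylated cRNA from 10 micrograms of total RNA, per the labels' protocols. The titles call the replicates biological, and each group holds 3 of them. Whether each replicate came from a separate animal is not otherwise stated, and the p-values treat the 3 numbers of a genotype as separate animals.

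The deposited values are on a log2 scale, with 1 value per probe set and array, as shown by their range. The probe sets belong to a gene-based chip definition with 1 probe set per gene. The background correction, normalization and summarisation behind these values are not given in the sources used here. The table holds 16539 probe sets. Of these, 64 were control probe sets, 15780 carried 1 gene symbol, 0 carried several, and 695 others were unnamed here. An Entrez identifier from the platform annotation was matched to the RefSeq gene table of the GRCm38.p6 assembly for 15752 of the named probe sets, and 0 symbols changed. No coordinates from that table were used. Genes were tested if their mean over the 12 arrays reached the 40th percentile of all probe sets, 5.57 on the log2 scale, which left 9496 genes. An array has no read depth, and the number of arrays limits the precision of each value.

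Differences were fitted with limma 3.58.1 (statmod 1.5.0) in R 4.3.3, on the log2 values as deposited, with the means of the 4 groups as the model, all 12 arrays in 1 fit (8 residual degrees of freedom) and empirical Bayes moderation. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p given for a gene comes from limma, is two-sided, and is adjusted over the 9496 genes unless stated. Standard errors (SE) are those of the moderated fit and SDs are taken over the 3 replicates. The fitted comparisons were wild-type IP against wild-type input, knockout IP against knockout input, knockout input against wild-type input, wild-type IP against knockout IP, and the interaction, in which the IP minus input difference of the knockout is subtracted from that of the wild type. The interaction is called specific enrichment. The figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

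The replicate numbers in the titles were checked for pairing before any calls were compared. After group means were removed, the 18 pairs of arrays with the same number in different groups had correlations across genes of 0.453 to 0.936 (median 0.672), and arrays with different numbers had correlations of -0.711 to 0.0685. All 12 arrays deviated most like those with their own number. The numbers therefore pair the samples. The pairing of an IP with its input comes from the series text. The sharing between genotypes comes from the values: input arrays of the same number in the 2 genotypes correlated at 0.983 to 0.990, and inputs of different numbers within a genotype at 0.862 to 0.957. A number is thus treated as a batch that holds 1 array of every group. The planned fit with a replicate block took the animal as the block for IP against input and for the interaction (4 residual degrees of freedom) and the number as the block between genotypes (6 residual degrees of freedom). Its values are given for the named genes and described lists where they change a call, and as counts of calls for the other lists. A simulation of unchanged groups drew every array independently and so ignored this pairing, and its values are not used here.

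The lists of genes and the rule for naming genes were fixed before the data were examined. For specific enrichment and for the inputs, the rule takes up to 10 called genes per direction with the largest change and no overlap between the compared replicates. For the other comparisons it takes up to 5. Where fewer pass, the genes with the smallest p in that direction fill up to 5 and are said not to pass. Cnot6l and Fgf21 are named throughout. From a list that is described, up to 4 members with the largest change are named. Another secreted factor that the rule names is not analysed here. Genes with only a clone name are counted and not named. Genes outside the rule are said to be named after their values were seen.

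The 20 lists were CCR4-NOT subunits and cofactors, mRNA decay factors, hepatokines, ATF4 targets of the integrated stress response, the unfolded protein response, immediate early genes, AU-rich inflammatory mRNAs, fatty acid oxidation, fatty acid synthesis, cholesterol synthesis, glucose metabolism, bile acids, xenobiotic cytochrome P450 enzymes, acute phase proteins, abundant plasma protein mRNAs, cytoplasmic ribosomal proteins, the mitochondrial respiratory chain, interferon-stimulated genes, the cell cycle and nuclear long noncoding RNAs. There were also 10 marker lists of liver cell types and zones. Each list was tested against the other genes with limma's camera at its preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether the members move one way on balance. These p-values were adjusted over the lists of a comparison.

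The alternatives were quantile normalization of all arrays or within inputs and within IPs, median centring, no filter on dim probe sets or a 60th percentile filter, unnamed probe sets included, the replicate block, the animal as a random block (within-animal correlation 0.597), the moderation with a trend and robust estimates, fits on the 6 arrays of a comparison alone, a required 2-fold change, and leaving out each array in turn. Fits with the number as a block over both fractions or within each fraction, the block on 6 arrays alone, and leaving out arrays or quantile normalization within the blocked fit were chosen after the arrays were seen to group by number. Pseudocounts and rules for several probe sets per gene had nothing to act on, because the values are log2 and each gene has 1 probe set.

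The fits were tested on simulated data made from the 9496 genes with their own means, number effects and residual spread, in which 50 genes each were moved up or down by log2 changes of 0.5, 1, 2 or 3. For specific enrichment, 0%, 0%, 2% and 38% of these were called, and 0%, 0%, 36% and 66% with the replicate block. For wild-type IP against knockout IP the shares were 0%, 2%, 34% and 80%, and 0%, 20%, 86% and 96% with the block, which also gave 13 false calls. For the inputs they were 0%, 0%, 30% and 86%, and 0%, 22%, 80% and 100% with the block. For wild-type IP against its input they were 0%, 2%, 34% and 84%, and for knockout IP against its input 0%, 2%, 36% and 84%. A list raised by 1 was found in every comparison, with 0 of 19 other lists called. The residuals were drawn independently for each gene. The simulation therefore does not test false list calls that come from correlation between the genes of a list.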

Results

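CNOT6L is a deadenylase subunit of the CCR4-NOT complex, which shortens the poly(A) tails of mRNAs. The arrays recorded which transcripts were recovered with an anti-CNOT6L antibody from primary hepatocytes, the parenchymal cells of the liver, of wild-type and Cnot6l knockout mice. Each of the 4 groups, wild-type input, wild-type IP, knockout input and knockout IP, had 3 arrays. The array medians lay between 6.31 and 6.45 on the log2 scale. The spread of values within an array was narrower in the IPs, with a mean SD of 2.35 in wild type and 2.27 in knockout, against 2.55 and 2.57 in the inputs. The bacterial poly-A control transcripts added to labelling reactions averaged 5.11 log2 units higher in the IP than in the input of the same preparation (4.55 to 5.90 over the 6 preparations), and the hybridisation controls 3.97 units higher (1.93 to 5.39). The gap between the 3′ and 5′ probe sets of Gapdh was 1.21 units wider in the IPs (0.85 to 1.95), and that of beta-actin 1.56 units wider (1.38 to 1.91). Each of these control differences between fractions was present in both genotypes.

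**Figure D1:**
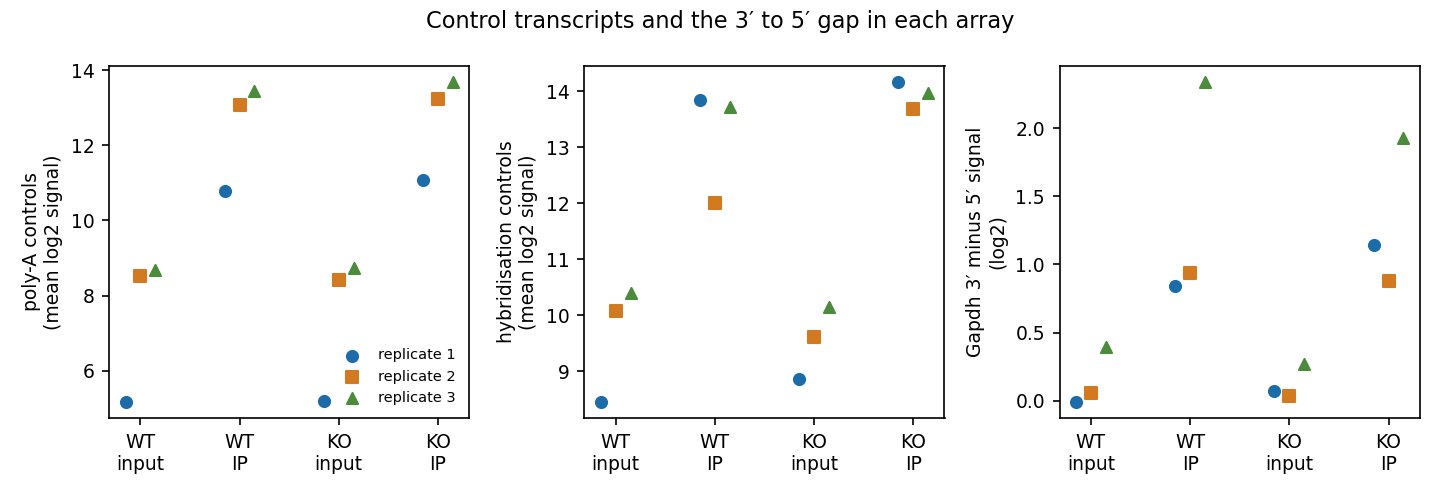
Mean log2 signal of the poly-A controls (left) and the hybridisation controls (middle), and the 3′ minus 5′ log2 signal of Gapdh (right), in each of the 12 arrays by group, with 1 point per array and symbols for the replicate number. The IP arrays lie above the input arrays of the same number in all 3 panels, with poly-A controls 4.55 to 5.90 units higher.

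Cnot6l itself had 1 probe set on the array. Its level was 9.02 ± 0.54 (SD, n = 3) in wild-type input and 9.23 ± 0.11 (SD, n = 3) in knockout input, with values of 8.44, 9.51 and 9.11 against 9.12, 9.23 and 9.34. The difference was 0.21 (95% interval -0.88 to 1.30), with a two-sided exact permutation p of 0.7, where 3 against 3 arrays can give no p below 0.1. In the IPs the values were 9.11, 10.65 and 8.85 in wild type and 9.29, 10.63 and 9.46 in knockout, a wild-type minus knockout difference of -0.26 (exact p 0.6). The Cnot6l signal was thus not lower in the arrays labelled knockout. Whether its probes lie in the deleted part of the gene is not given in the sources used here, so this probe set checks nothing about the labels, and the directions that follow rest on the genotype labels.

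Specific enrichment asks which transcripts were more enriched over input in wild type than in the negative control. The transcript of Tec, a cytoplasmic tyrosine kinase, was 10.4-fold more enriched in wild type, a log2 difference of 3.37 ± 0.40 (SE) with an adjusted p of 0.0219. The 3 same-number differences were 3.16, 3.78 and 3.18. Tec stood at 11.77 ± 0.35 (SD, n = 3) in wild-type IP and between 8.41 and 8.63 on average in the other 3 groups. The next smallest p-values belonged to Nfkbia, which encodes the NF-κB inhibitor IκBα, with 3.34 ± 0.51, and to Fgf21, which encodes a hormone secreted by the liver, with 3.13 ± 0.49 (8.75-fold). Both had an adjusted p of 0.116 and did not pass, with same-number differences of 2.92, 4.0 and 3.09 for Nfkbia and 3.64, 2.84 and 2.91 for Fgf21.

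In this comparison 1 gene was called higher and 0 lower by limma, and 174 genes were higher and 14 lower at an unadjusted p under 0.05. G0s2, an inhibitor of the triglyceride lipase ATGL, and Cdk7, a kinase of the general transcription factor TFIIH, had values of 2.79 ± 0.53 and 2.3 ± 0.42 (adjusted p = 0.365 for both). In the other direction the smallest p-values were those of Foxf1 (-1.18), Ppm1l (-1.23), Tonsl (-1.17), Allc (-1.10) and Pou3f4 (-0.99), all at an adjusted p of 1.0. These lower genes were dim in wild-type IP, with means of 5.42 to 5.98, and had means of 6.33 to 6.89 in knockout IP. With the animal as replicate block 2 genes were called, Tec (adjusted p = 0.0103) and Adamts1, a secreted metalloprotease named after its values were seen (3.25, adjusted p = 0.0460 with the block and 1.0 without it). Nfkbia and Fgf21 had adjusted p = 0.0571 with the block, Cdk7 0.0840 and G0s2 0.118. Blocks by number, chosen after the arrays were seen to group by number, called 27 genes with the number shared by both fractions and 34 with the number within each fraction. Nfkbia and Fgf21 (both 0.0159 and 0.00907), Cdk7 (0.0283 and 0.0377) and G0s2 (0.0318 and 0.0170) passed in both of these fits. Over all alternatives the adjusted p ran from 0.000119 to 0.142 for Tec, from 0.00276 to 0.549 for Fgf21, from 0.00276 to 0.522 for Nfkbia, from 0.0121 to 1.0 for Cdk7 and from 0.0145 to 1.0 for G0s2. The call of Tec held when wild-type IP replicate 1 or knockout IP replicate 1 was left out and was lost when any other single array was, with an adjusted p of up to 0.142 and differences of 3.18 to 3.50.

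**Figure D2:**
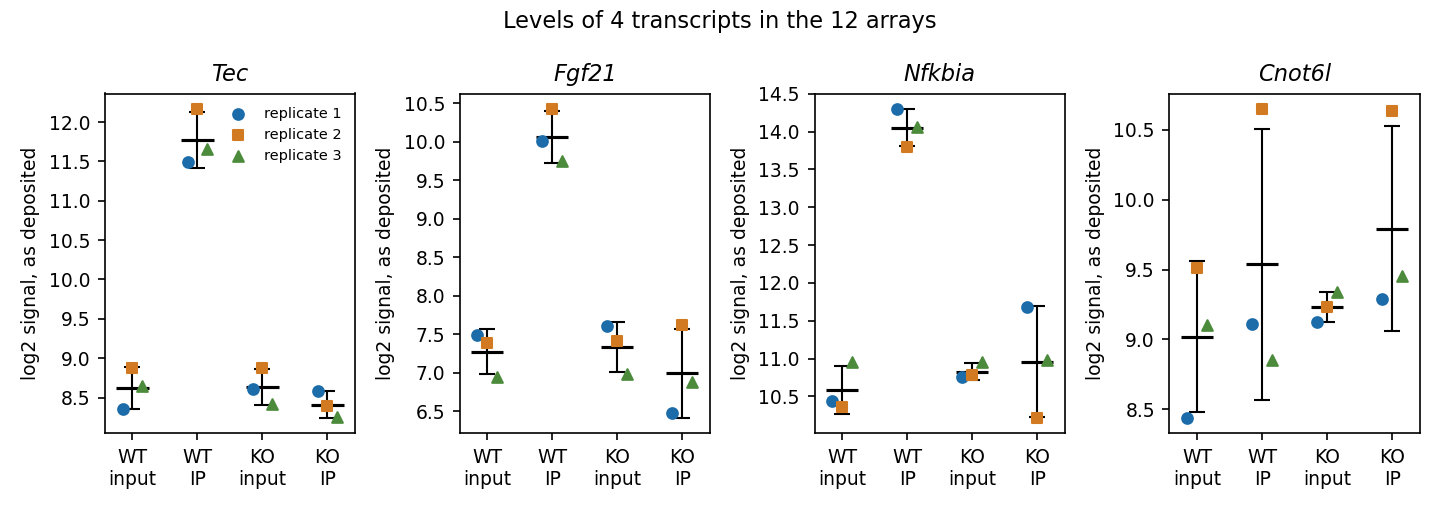
Log2 signal as deposited for Tec, Fgf21, Nfkbia and Cnot6l in the 4 groups, with 1 point per array, symbols for the replicate number, the horizontal bar at the mean and whiskers of 1 SD (n = 3). For Tec, Fgf21 and Nfkbia the 3 wild-type IP arrays lie above all other arrays, and for Cnot6l the groups overlap.

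Among the gene lists, the immediate early genes, which cells switch on within minutes of a stimulus, stood apart in specific enrichment. Of 36 tested members 33 had positive values, with a median of 1.03 and within-number medians of 1.12, 1.08 and 0.92. None passed over all genes tested, 6 passed as higher adjusted over the list alone, and 20 did so with the replicate block. Zfp36, which encodes the AU-rich element binding protein tristetraprolin, had the largest value (3.48 ± 0.79), followed by Fos (2.60), Ier3 (2.52) and Ccn1 (2.32), none of which passed over all genes in the fit without a block. With the number as a block shared by both fractions Zfp36 (adjusted p = 0.0383) and Ccn1 (0.0283) passed, and with the number within each fraction Fos did (0.0433). The list was called by camera (adjusted p = 1.16e-26), and its call held with an estimated correlation (adjusted p = 0.0187). It missed the threshold with fry (adjusted p = 0.0615). With the replicate block the estimated correlation gave an adjusted p of 0.0729 and fry 0.0217.

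The AU-rich inflammatory mRNAs had a median of 0.94 over 15 members, 11 of them positive and 1 passing adjusted over the list alone (8 with the block), with Nfkbia and the chemokine gene Cxcl2 (2.57, not passing) at the top. Camera gave an adjusted p of 0.00191, which became an adjusted p of 0.902 with an estimated correlation. CCR4-NOT subunits and cofactors (13 members, median 0.20) and mRNA decay factors (26 members, median 0.23) each had an adjusted p of 0.0278, which became 0.902 and 0.363 as adjusted p with an estimated correlation and 0.106 and 0.0986 with the replicate block. At the top of the former were the antiproliferative cofactor Btg2 (2.33) and the deadenylase Cnot8 (1.84), both passing adjusted over the list alone. From input to IP, Btg2 went from 10.45 to 11.71 in wild type and from 10.52 to 9.45 in knockout. Cnot8 went from 8.25 to 10.25 and from 8.20 to 8.35. Over all genes neither passed with the replicate block (adjusted p = 0.0650 and 0.212). Both passed with the number as a block within each fraction (adjusted p = 0.0168 for both). With the number shared by both fractions Btg2 passed (adjusted p = 0.0245) and Cnot8 did not (0.0872). At the top of the latter were Zfp36 and Zfp36l1 (1.53, not passing). Zfp36l1 was not higher in wild-type IP than in its input (10.23 against 10.34). Its value came from the knockout, with 8.65 in the IP against 10.28 in the input. Of 60 tested respiratory chain genes 8 were positive, with a median of -0.12, an adjusted p of 0.000503 and an adjusted p of 0.902 with an estimated correlation. Its largest values were those of Ndufa12 (-0.86) and Ndufs5 (-0.39), which did not pass. Hepatokines, the secreted proteins of hepatocytes, had a median of 0.04 over 25 members and were not called (adjusted p = 0.629), although Fgf21 and the activin subunit gene Inhbe (2.33) passed adjusted over the list alone.

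Wild-type IP against wild-type input gives the enrichment before the negative control is taken into account. Here 10 genes were called higher and 0 lower, and 435 were higher and 573 lower at an unadjusted p under 0.05. Nfkbia rose by 3.47 ± 0.36 (SE; adjusted p = 0.00270), Tec by 3.15 ± 0.28 (adjusted p = 0.00113) and G0s2 by 2.95 ± 0.37 (adjusted p = 0.00880). Taf5, a subunit of the transcription factor TFIID, rose by 2.86 (adjusted p = 0.0474) and the cytokine signalling inhibitor Socs3 by 2.80 (adjusted p = 0.0124). Fgf21 rose by 2.79 ± 0.35 (6.90-fold, adjusted p = 0.00880). The remaining called genes, named after their values were seen, were the transcription factor Irf1 (2.22), Cnot8 (2.00), the MAP kinase phosphatase Dusp1 (1.74) and the FGF receptor adaptor Frs3 (1.67). All 10 were higher in 3 of 3 preparations. The lower values with the smallest p were those of the sulfhydryl oxidase gene Qsox1 (-2.91, adjusted p = 0.0533), the mitochondrial elongation factor gene Gfm2 (-1.89), the basigin gene Bsg (-1.58), the Arp2/3 subunit gene Arpc4 (-1.64) and Dedd (-1.37), which did not pass. All 5 passed with the replicate block (adjusted p of 0.0127 to 0.0187). They were also lower in the IP than in the input of the negative control. There Qsox1 went from 9.85 to 7.36, Gfm2 from 8.48 to 6.97, Bsg from 12.92 to 11.37, Arpc4 from 10.43 to 8.95 and Dedd from 8.43 to 7.57.

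Of the 10 calls, between 2 and 8 remained when 1 array was left out, with 2 remaining without wild-type input replicate 1 or 2. The adjusted p of Fgf21 rose to 0.0580, 0.0578 and 0.0508 without wild-type input replicates 1, 2 and 3, and Tec and Nfkbia stayed below the threshold in each of these fits. A limma fit on the 6 arrays of this comparison alone kept 1 of the 10, Nfkbia (adjusted p = 0.0473), with Tec at 0.0579 and Fgf21 at 0.101. With the replicate block on these 6 arrays all 10 were kept. With the replicate block 229 genes were called higher and 438 lower, which became 172 and 159 when the arrays were quantile normalized as well. As deposited, the median of all genes tested was -0.11, and the groups did not overlap in 15.3% of genes, where chance gives 10% for 3 against 3 unpaired arrays and another share for arrays paired by number.

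Immediate early genes were higher in wild-type IP than in wild-type input by camera, with 31 of 36 members positive, a median of 0.70 and an adjusted p of 6.29e-11 (adjusted p = 0.224 with an estimated correlation, 0.0857 by fry). Socs3 and Dusp1 passed over all genes, 6 members passed adjusted over the list alone, and Zfp36 had 2.55 without passing. With the replicate block Zfp36 passed (adjusted p = 0.0127), as did 10 members over all genes and 18 over the list alone, and fry gave the list an adjusted p of 0.00757 and an estimated correlation one of 0.165. AU-rich inflammatory mRNAs (median 0.56, adjusted p = 0.000537), CCR4-NOT subunits and cofactors (0.26, adjusted p = 0.00562) and mRNA decay factors (0.31, adjusted p = 0.00800) lay on the same side, with Cnot7 (-1.36), Edc3 (1.51) and Cxcl2 (2.13) not passing over all genes without the block and passing with it (adjusted p = 0.0389, 0.0157 and 0.0173). Abundant plasma protein mRNAs lay on the other side, with a median of -0.55, 3 of 25 members positive and 3 passing as lower adjusted over the list alone. Their adjusted p was 0.000522, with Vtn at -1.12 and Plg at -1.06, neither passing over all genes without the block and both passing with it (adjusted p = 0.0211 and 0.0387). With the block 5 members passed as lower over all genes and 12 over the list alone. The respiratory chain had a median of -0.52, with 6 of 60 members positive, an adjusted p of 1.93e-07, and Sdhd at -1.18 and Ndufb2 at -1.16 without passing. With the block Ndufb2 passed (adjusted p = 0.0378), as did 4 members as lower over all genes and 12 over the list alone. The members named as lower were also lower in the IP than in the input of the negative control. There Vtn went from 11.28 to 10.46, Plg from 9.09 to 8.29 and Cnot7 from 7.69 to 6.05. Sdhd went from 10.87 to 9.70 and Ndufb2 from 11.68 to 10.59. With an estimated correlation these lists had an adjusted p of 0.629 (AU-rich, plasma proteins and respiratory chain), 0.628 (CCR4-NOT) and 0.224 (decay factors), so none of the 6 calls held. Fry called 0 of the 20 lists without the block and 11 with it, among them plasma proteins (adjusted p = 0.000107) and the respiratory chain (adjusted p = 0.0269), and with the block an estimated correlation called 0. Over the 6 preparations of both genotypes, the poly-A controls were 4.55 to 5.90 units higher and the Gapdh 3′ to 5′ gap 0.85 to 1.95 units wider in the IP than in the input.

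Knockout IP against knockout input compares the background of the precipitation with its input, transcript by transcript. The array medians were alike in all groups, so these values do not give the amount of RNA recovered. By limma 0 genes were called higher and 0 lower, with 282 higher and 760 lower at an unadjusted p under 0.05. The smallest p-values were those of Rasal1 (1.77), Cdrt4 (1.40), Slc1a7 (1.43), Ces1h (1.32) and Cyp2j11 (1.16) on the higher side, and of Ric8b (-1.90, adjusted p = 0.0714), the cell death gene Pmaip1 (-1.99), the Rag GTPase gene Rraga (-3.21), St3gal4 (-2.05) and the RNA-binding protein gene Mex3d (-2.89) on the lower. All 10 passed with the replicate block (adjusted p of 0.00292 to 0.0237). Those on the higher side were dim, at 4.97 to 5.54 in knockout input, below the filter of 5.57, and 6.35 to 6.97 in knockout IP. They were also higher in wild-type IP than in wild-type input. The mean 10th percentile of the arrays likewise rose, from 3.46 in knockout input to 4.05 in knockout IP. Fgf21 had -0.34 ± 0.35 (adjusted p = 0.767), and the immediate early genes had a median of -0.46 and were not called (adjusted p = 0.327). With the replicate block fry called the immediate early genes lower (adjusted p = 0.0392), with 5 members passing as lower over all genes, and an estimated correlation did not (adjusted p = 0.688). With the replicate block 69 genes were called higher and 501 lower, which became 30 in all after quantile normalization. As deposited, the median of all genes was -0.21 here, and quantile normalization moved it to -0.04, the largest such shift in any comparison (0.165). Of the 20 lists camera called 0, and with the replicate block fry called 9, the immediate early genes among them, and an estimated correlation called 0. The groups did not overlap in 15.4% of genes. Across genes, the IP minus input differences of the 2 genotypes correlated with a Pearson r of 0.668 and a Spearman rho of 0.693. The differences come from separate arrays that share replicate numbers, and the value for unchanged paired arrays was not computed.

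Wild-type IP against knockout IP sets the precipitates side by side without the inputs. In this comparison 24 genes were called higher in wild type and 0 lower, with 454 higher and 58 lower at an unadjusted p under 0.05. The 5 largest were Tec (3.36 ± 0.28, adjusted p = 0.000557), Zfp36 (3.33 ± 0.56, adjusted p = 0.0368), the cyclin gene Ccng2 (3.20 ± 0.43, adjusted p = 0.0152), Nfkbia (3.09 ± 0.36, adjusted p = 0.00605) and Fgf21 (3.07 ± 0.35, adjusted p = 0.00605). Fgf21 stood at 10.06 ± 0.34 (SD, n = 3) in wild-type IP and 6.99 ± 0.58 (SD, n = 3) in knockout IP, an 8.41-fold difference with same-number values of 3.53, 2.81 and 2.87. Other called genes, named after their values were seen, included G0s2 (2.74), Btg2 (2.26), Socs3 (2.20), Cdk7 (2.06), Irf1 (2.01), Dusp1 (1.91), Cnot8 (1.90) and the transcription factor gene Csrnp1 (1.83), and 3 of the 24 have only a clone name. All 24 were higher in 3 of 3 number pairs. The lower values with the smallest p were those of Mterf2 (-1.42, adjusted p = 0.108), Tonsl (-1.30), Ppm1l (-1.10), Foxf1 (-0.99) and Zfp105 (-0.98), which did not pass without the replicate block and passed with it (adjusted p of 0.0116 to 0.0414). These lower genes were dim in wild-type IP, with means of 4.86 to 5.90, and had means of 6.28 to 6.89 in knockout IP. The low end of the arrays was likewise lower in wild-type IP, with a mean 10th percentile of 3.86 against 4.05 in knockout IP.

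With the number as replicate block 221 genes were called higher and 12 lower, all 24 among the former. When 1 array was left out, between 4 and 12 of the 24 remained, with 4 remaining without wild-type IP replicate 2, wild-type IP replicate 3 or knockout IP replicate 3, and Tec, Nfkbia and Fgf21 stayed below the threshold in each of these fits. A fit on the 6 IP arrays alone called 0 genes without the block and 7 with it. The median residual SD after number and genotype were removed was 0.283 in the IPs and 0.136 in the inputs, so a spread pooled over both fractions is smaller than that of the IPs alone. The groups did not overlap in 6.79% of genes. The chance share of 10% holds for unpaired arrays, and these are paired by number, so the share has no chance value here.

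**Figure D3:**
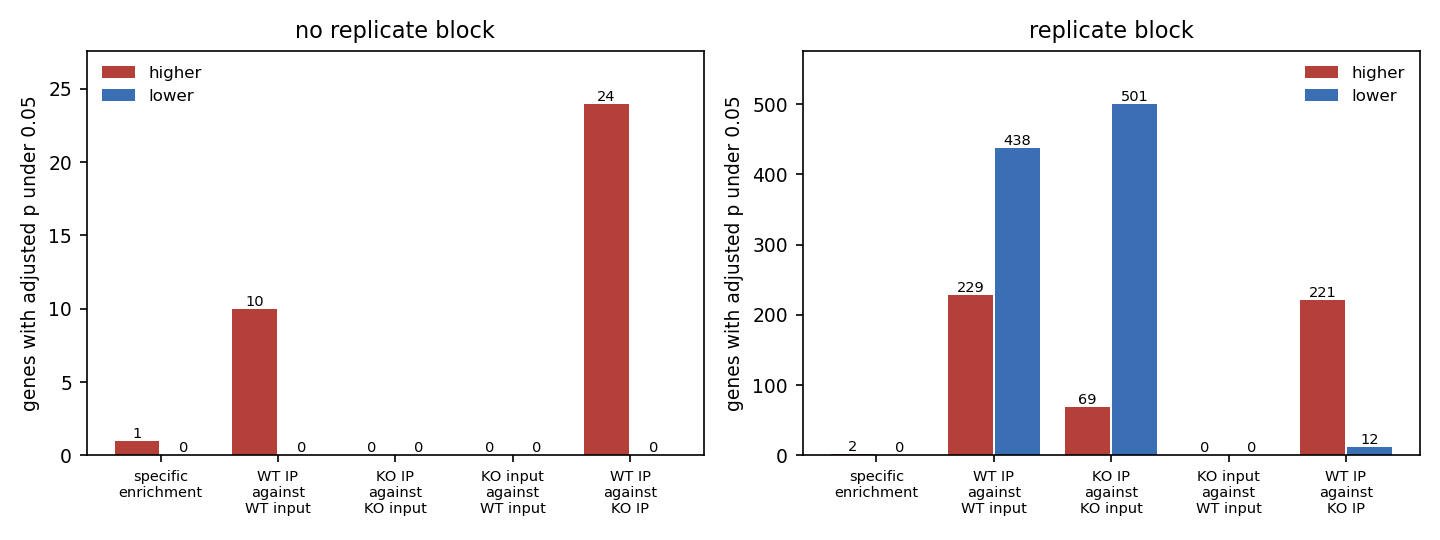
Number of genes with an adjusted p under 0.05 in each of the 5 comparisons, higher and lower, without a replicate block (left) and with it (right, on another scale). Without the block, wild-type IP against knockout IP gave 24 genes and wild-type IP against its input 10, and the inputs gave 0 in both fits.

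All 36 immediate early genes tested had a positive wild-type minus knockout difference in the IPs, with a median of 1.03 and within-number medians of 1.11, 1.27 and 0.85. Over all 39 members on the array, those under the filter included, the median was 0.96. Zfp36, Socs3, Dusp1 and Csrnp1 passed over all genes, 17 members passed adjusted over the list alone, and 17 passed over all genes with the block. Dusp6 (2.60), Ier3 (2.51) and Ccn1 (2.23) did not pass without it. The adjusted p of the list was 2.49e-26 by camera, 0.0195 as adjusted p with an estimated correlation and 0.00693 by fry. With the block the adjusted p was 0.111 with an estimated correlation and 0.00245 by fry, which called 7 of the 20 lists with the block and 1 without. In the inputs the wild-type minus knockout median of the list was -0.0072. In the same arrays the wild-type minus knockout difference was -0.29, -0.17 and -0.26 for the poly-A controls, -0.33, -1.67 and -0.26 for the hybridisation controls, and -0.30, 0.06 and 0.42 for the Gapdh 3′ to 5′ gap. The respiratory chain had a median of -0.21 with 3 of 60 members positive (adjusted p = 1.66e-06; adjusted p = 0.975 with an estimated correlation), with Ndufa12 at -0.97 and Ndufs5 at -0.58 not passing. The AU-rich inflammatory mRNAs had a median of 0.50 (adjusted p = 0.0574, and 0.00372 with the block, where an estimated correlation gave an adjusted p of 0.439). Of their 25 members on the array 15 were tested, and over all 25 the median was 0.38.

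**Figure D4:**
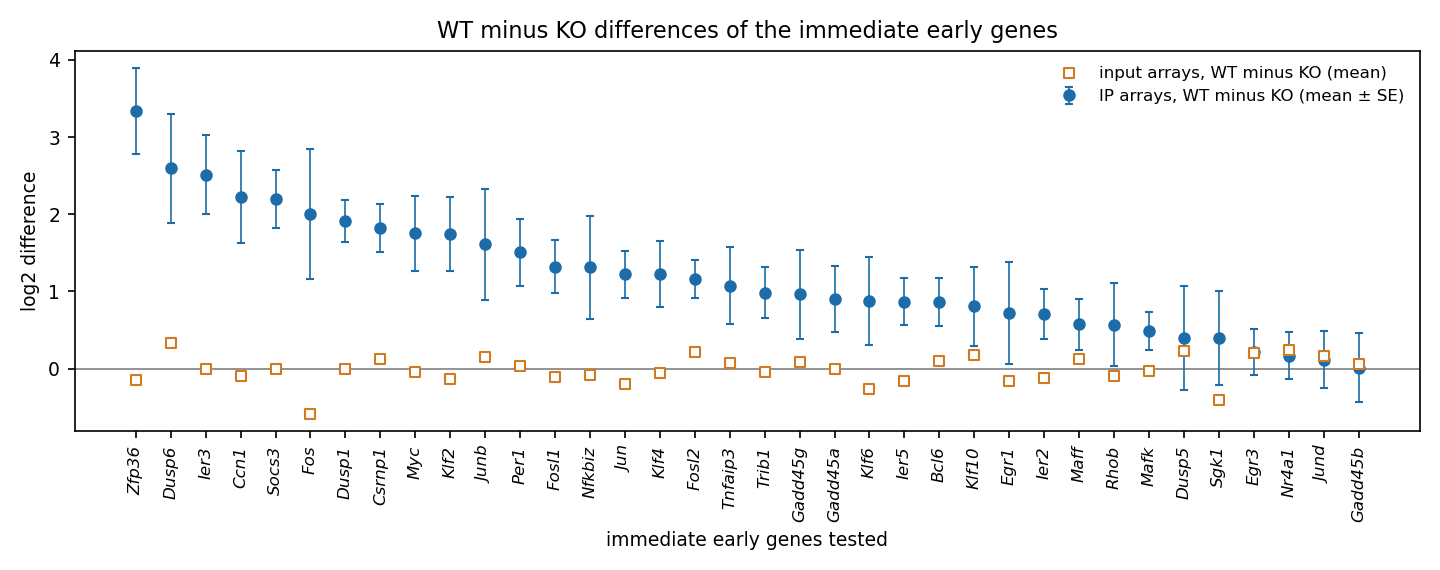
Wild-type minus knockout log2 difference of each of the 36 immediate early genes tested, in the IP arrays (filled circles, mean ± SE) and in the input arrays (open squares, mean), ordered by the former. The IP differences reach 3.33 for Zfp36 and have a median of 1.03, and those in the inputs have a median of -0.0072.

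Knockout input against wild-type input compares steady-state transcript levels in the hepatocytes. By limma 0 genes were called higher and 0 lower, with or without the replicate block, and 3 were higher and 2 lower at an unadjusted p under 0.05 (23 and 30 with the block). The median residual SD after number and genotype were removed was 0.136 in the inputs and 0.283 in the IPs. A spread pooled over both fractions is thus larger than that of the inputs. Fits on the 6 input arrays alone, with or without the block, also called 0 genes. The groups did not overlap in 1.62% of genes, a share with no chance value here, since 10% holds for unpaired arrays. Fgf21 differed by 0.06 ± 0.35, an SE from the fit without the block. By number its levels were 7.60, 7.41 and 6.98 in knockout input and 7.49, 7.39 and 6.94 in wild-type input. The smallest p-values belonged to the chemokine gene Cxcl10 (1.30), Obp2a (1.5), St3gal6 (1.20), Ces1f (0.89) and Zfp229 (0.77) on the higher side, and to Cryab (-0.78), the glucokinase regulator Gckr (-0.96), the choline transporter Slc44a1 (-0.78), Gpx3 (-0.63) and the retinoic acid hydroxylase Cyp26a1 (-2.00) on the lower, all at an adjusted p of 1.0. Arrays of one number resembled each other across genotypes more than those of one genotype did.

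Abundant plasma protein mRNAs were lower in knockout input as a list, with a median of -0.18, 4 of 25 members positive and within-number medians of -0.19, -0.19 and -0.23. Camera gave an adjusted p of 3.47e-06, and an estimated correlation an adjusted p of 0.551. With the number as block the adjusted p was 7.55e-11, or 0.00488 with an estimated correlation and 0.00109 by fry, which gave 0.997 without the block. None of its members passed, also when adjusted over the list alone. The complement gene C9 (-0.62), the plasminogen gene Plg (-0.52), Cfb (-0.52) and Apoc2 (-0.45) had the largest values. Acute phase proteins had a median of -0.13 with 6 of 25 members positive (adjusted p = 4.40e-05; adjusted p = 0.551 with an estimated correlation, and 0.0115 with the block and an estimated correlation), and fry did not call them (adjusted p = 0.997, and 0.0551 with the block). Within numbers the medians were -0.08, -0.05 and -0.26, and the serum amyloid genes Saa2 (-0.85), Saa3 (-0.61) and Saa1 (-0.42) and the orosomucoid gene Orm2 (-0.48) led without passing. Cytoplasmic ribosomal protein genes had a median of 0.18 with 15 of 16 members positive (adjusted p = 0.000165; adjusted p = 0.754 with an estimated correlation), led by Rpl15 (0.47) and Rpl31 (0.32). The respiratory chain (median 0.08, led by Atp5o at 0.23 and Ndufs8 at 0.20) and AU-rich inflammatory mRNAs (0.14, with Ccl7 at 0.46) each had an adjusted p of 0.0407, and an adjusted p of 0.754 with an estimated correlation.

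Of the 10 marker lists, 7 had enough measured members to be tested, and camera called 0 in any comparison without the block. In knockout input against wild-type input with the block, camera called the hepatocyte (median -0.05, adjusted p = 0.0421), stellate cell (-0.17, adjusted p = 0.0145) and cholangiocyte markers (-0.24, adjusted p = 0.0145), and these became an adjusted p of 0.167, 0.179 and 0.167 with an estimated correlation. Within numbers the stellate cell median was -0.30, -0.76 and 0.09 and the cholangiocyte median 0.15, -0.86 and -0.15, in the same arrays in which the plasma protein list was lower. Of 14 Kupffer cell and macrophage markers on the array 2 reached the filter, and of the neutrophil and erythroid markers 1 each, too few for a test.

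The overlap of enrichment with a rise in the knockout input asks whether transcripts recovered more in wild type are higher in hepatocytes without CNOT6L. Whether CNOT6L holds these transcripts was not tested. The number of genes called in both was 0, for specific enrichment as for wild-type IP against knockout IP, since 0 genes were called in the inputs. The 24 genes higher in wild-type IP than in knockout IP had a mean knockout minus wild-type input difference of -0.05 (95% interval over the 3 numbers -0.17 to 0.07), with 12 of 24 higher in knockout and a fry p of 0.707, a camera p of 0.0495 and a camera p of 0.287 with an estimated correlation. For the 221 genes called with the block the mean was -0.03 (-0.16 to 0.10), with 95 of 221 higher in knockout, a fry p of 0.601, a camera p of 0.0151 and a camera p of 0.211 with an estimated correlation. These p-values are not adjusted. The 221 genes include Mex3d, which was below its input in wild-type IP (7.03 against 7.79) and further below it in knockout IP (4.58 against 7.46). Across the 9496 genes the wild-type minus knockout IP difference correlated with the knockout minus wild-type input difference with r = -0.174 (rho = -0.176). These differences share no array, but their IPs and inputs are portions of the same preparations, and the value for unchanged paired arrays was not computed.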

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

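The tests of the input difference and of RNA integrity for the immediate early genes, and the test of the hepatocyte share for the plasma proteins, were chosen after the result was seen. The interaction of fraction and genotype singled out Tec, with a difference in enrichment of 3.37, and 5 lists by their medians: immediate early genes (1.03), AU-rich inflammatory mRNAs (0.94), mRNA decay factors (0.23), CCR4-NOT subunits and cofactors (0.20) and the respiratory chain (-0.12). Of these lists, the immediate early genes alone kept an adjusted p under 0.05 with an estimated correlation (0.0187), and with the replicate block none did (0.0729 for the immediate early genes).

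Immediate early genes were higher in wild-type IP than in knockout IP, by a median of 1.03 over 36 members, a call lost with the replicate block and an estimated correlation (adjusted p = 0.111). Their medians against input were 0.70 in wild type and -0.46 in knockout. Fry with the block called the list higher in the former and lower in the latter (adjusted p = 0.0392 in knockout). With an estimated correlation it was called in neither, with or without the block. Compression of the knockout IP arrays at a given expression level is argued against by 10000 lists matched on mean level, of which 0% had a median as high (highest 0.24). A difference between the animals already in the input RNA is argued against by the wild-type minus knockout input median of -0.0072. The within-number medians were -0.008, 0.14 and -0.05, and the 95% interval of their mean was -0.21 to 0.27. A difference in RNA integrity between the precipitates, as read from the Gapdh 3′ to 5′ gap, is argued against by the lowest within-number median of 0.85. That gap differed in both directions over the same numbers, but it comes from 1 transcript. The poly-A controls (-0.29, -0.17 and -0.26) and hybridisation controls (-0.33, -1.67 and -0.26) were lower in wild-type IP in every number. The Gapdh test does not cover what set these controls apart, which stays open. Binding through CNOT6L, a biological difference that the design names, stays open, as does any difference in the precipitation itself, which these arrays cannot tell apart from it.

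Abundant plasma protein mRNAs were lower in knockout input, by a median of 0.18 over 25 members, by camera (adjusted p = 3.47e-06) but not with an estimated correlation (adjusted p = 0.551) or by fry (0.997), and by all 3 tests with the replicate block. Compression of the knockout input arrays is argued against by their spread, which was no narrower than in wild-type input (mean SD 2.57 against 2.55). Of lists matched on mean level in 20 bins, 0% had a median as low (lowest -0.08). Genes within a bin still differ in level, so the matching is coarse for the brightest transcripts. A lower share of hepatocytes in the knockout inputs would raise the markers of other cell types, and 24 of these had a median of -0.16. The within-number medians were 0.03, -0.39 and -0.07, and the 95% interval of their mean was -0.70 to 0.41, so a lower share stays open. A change of liver secretory mRNAs in animals without Cnot6l stays open as an untested hypothesis.

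Signal also appeared in probe sets outside the gene comparisons. The poly-A control transcripts were 5.11 log2 units higher and the hybridisation controls 3.97 units higher in the IPs than in the inputs. In wild-type IP against knockout IP, 1 of 368 unnamed probe sets was called.

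Arrays were regrouped in the other ways the design allows, with too few splits for a share under 0.05. Of the 10 splits without the block, 4 parted the arrays of each number, the real split included. The others among these 4 called 0 genes in every comparison. As many genes as in the real grouping were called in 1 of 10 splits for specific enrichment (1 gene, highest other 0), 1 of 10 for wild-type IP against its input (10, highest other 0), 10 of 10 for knockout IP against its input (0, highest other 0), 10 of 10 for the inputs (0, highest other 0) and 1 of 10 for wild-type IP against knockout IP (24, highest other 1). With the replicate block the splits were 1 of 4 (2 genes, highest other 0), 1 of 4 (667, highest other 0), 1 of 4 (570, highest other 0), 4 of 4 (0, highest other 0) and 1 of 4 (233, highest other 1) in the same order.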

How the results depend on the processing

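The fits with the number as a block over both fractions or within each, the block on 6 arrays alone, and all alternatives within the blocked fit were chosen after the result was seen. For the 107 named gene results, 2471 alternatives were run. Of these 2133 kept direction and side of the threshold, 187 no longer passed, 128 newly passed and 23 reversed. The mean of probe sets, the removal of probe sets by suffix and the pseudocounts were not run, since nothing in the values called for them.

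The number of genes called changed with the block, which removes the spread between numbers. Specific enrichment went from 1 gene to 2 with the replicate block, 33 with a random block, 27 with the number as a block over both fractions and 34 with the number within each, and to between 0 and 4 without 1 array. Within the blocked fit it was 1 after quantile normalization and 0 to 6 without 1 array. Wild-type IP against its input went from 10 to 16 after quantile normalization, 667 with the block, 898 with a random block, 1108 with the number over both fractions, 1 on its 6 arrays alone, 933 on these with the block, and 2 to 14 without 1 array. Within the blocked fit it was 331 after quantile normalization and 1 to 938 without 1 array. Knockout IP against its input went from 0 to 52 with no filter, 570 with the block, 933 with a random block, 1073 with the number over both fractions, 8 on its 6 arrays with the block, and 0 to 2 without 1 array. Within the blocked fit it was 30 after quantile normalization and 6 to 379 without 1 array. Wild-type IP against knockout IP went from 24 to 233 with the block, 7 with a random block, 0 on its 6 arrays alone, 7 on these with the block, and 4 to 16 without 1 array. Within the blocked fit it was 79 to 225 without 1 array. The inputs gave 0 in every alternative. Leaving out an array takes 1 residual degree of freedom from the spread of every gene, and beyond this the cause was not tested.

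The immediate early list had an adjusted p of 0.0615 by fry in specific enrichment, and in wild-type IP against its input 0.224 with an estimated correlation and 0.0857 by fry, where fry with the replicate block gave 0.00757. Of the named genes, only genes that had not passed reversed, each without 1 array, and the cause was not tested. Cnot6l ranged from -0.60 to 0.38 in specific enrichment, -0.038 to 0.86 in wild-type IP against its input, -0.077 to 0.46 between the inputs and -0.81 to 0.16 between the IPs. Between the inputs the ranges were -0.11 to 0.23 for Fgf21, -0.44 to 1.48 for Ccl7, -1.32 to 0.035 for Saa3, -1.48 to 0.072 for C9, -1.03 to 0.039 for Plg, -1.11 to 0.055 for Cfb, -0.00096 to 0.93 for Rpl15, -0.16 to 0.58 for Atp5o and -0.12 to 0.49 for Ndufs8.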

Other observations

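No test in this part was chosen after the result was seen. Lists of liver metabolism moved little in specific enrichment and none of them was called. Their medians were -0.04 for fatty acid oxidation (27 genes, mean 0.01), 0.05 for fatty acid synthesis (15 genes), 0.07 for cholesterol synthesis (17 genes), 0.06 for glucose metabolism (17 genes), -0.10 for bile acids (15 genes) and -0.09 for cytochrome P450 enzymes (15 genes). Camera ranked fatty acid synthesis, cholesterol synthesis and glucose metabolism as lower than the other genes although their medians were positive. Stress and secretory lists were likewise not called: targets of ATF4 in the integrated stress response (0.19), the unfolded protein response (0.18), acute phase proteins (-0.04, mean 0.04) and plasma proteins (-0.17). Ribosomal protein genes had a median of 0.14, interferon-stimulated genes -0.02 (mean 0.15), cell cycle genes 0.02 (mean -0.15) and nuclear long noncoding RNAs -0.01.

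Markers of cell types had medians in specific enrichment of -0.02 for hepatocytes, 0.04 for sinusoidal endothelial cells, 0.04 for stellate cells (mean -0.13), 0.19 for cholangiocytes, 0.07 for lymphocytes, 0.27 for pericentral and 0.31 for periportal hepatocytes, none called. In knockout IP against its input the pericentral median was -0.75 and the hepatocyte median -0.39, and in wild-type IP against its input they were -0.49 and -0.49. With the number as block, cell cycle genes were called lower in knockout input (median -0.10, adjusted p = 0.0195; adjusted p = 0.603 with an estimated correlation), with -0.73, 0.03 and 0.32 within numbers.

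In the control probe sets, arrays with the number 1 stood apart from the others in both genotypes. Their poly-A control means were 5.16 and 5.19 in the inputs, against 8.42 to 8.72 in the other inputs. Their gap between the 3′ and 5′ probe sets of the Dap control was 4.5, 5.31, 4.64 and 4.87 over the 4 groups, against 0.85 to 2.42 elsewhere, and their 18S signal in the inputs was 6.82 and 7.23 against 11.65 to 12.97. In the gene values the inputs with the number 3 stood apart instead, correlating with the inputs of the other numbers at 0.862 to 0.893, where those of numbers 1 and 2 correlated with each other at 0.929 to 0.957.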
